A study of Mus musculus with 12 samples.

How the data were processed

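RNA from sorted mouse thymocytes was measured on Affymetrix arrays in 12 samples, which fall by their titles into 6 groups of 2: WT and IkL/L cells at the DN3, DN4 and DP stages. The design text states that cells of 3 mice were combined for sorting. It does not state whether the arrays of a group come from separate pools, so each array is treated as a replicate, and the spread between arrays need not hold all variation between mice. The labels describe biotin-labelled cRNA made by a protocol with 2 rounds of amplification, in 3 labelling series with different amounts of RNA. The labels do not assign those series to samples, so a labelling batch was not tested.

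The authors processed the arrays with RMA per the processing notes (version not given), a method that corrects background, quantile normalizes the probes and summarises each set. Whether all arrays were normalized in a single run is not stated. The deposited values are log2 signals, 1 per probe set and array, and no array had a column that could not be matched to a sample. The scale was tested on the values, which ran from 2.68 to 14.7. The 75th percentile differed between arrays, from 7.34 on WT DN4 replicate 1 to 7.57 on WT DP replicate 2, so the deposited values do not share a distribution, and a second quantile normalization was among the alternatives. Array signal has no read depth. Precision was set by the number of arrays and by the background, and genes near the array floor cannot show a further fall. The signal of a gene below the median of its array may be mostly background, so a difference from such a level is a difference of signals and a lower limit of that in RNA.

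Of 45099 probe sets, 34958 carried 1 gene symbol, 932 several and 9209 none in the platform table. The gene ID of 34754 was found in the reference gene table, which changed 0 symbols. Probe sets with no or several symbols were left out of the gene counts. Each of 18194 genes was represented by the probe set with the highest mean over all arrays, and 11649 genes with at least 2 arrays at or above the median of their array were tested. The remaining 6545 were not. Genome positions are not given, since no build is named for the array.

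Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0 for random blocks): a linear model with 1 mean per group over all 12 arrays, moderated by an empirical prior (6 residual and 5.67 prior degrees of freedom). The contrasts were IkL/L minus WT at each stage and averaged over stages, the difference of that effect between DP and DN3 cells, a moderated F test of any difference between stages, and the step from DN3 to DN4 and from DN4 to DP in each genotype. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes of a contrast. Differences are on the log2 scale, and SE is the moderated standard error. Every p value of a gene or probe set in the text comes from limma.

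Before the data were examined, the groups, contrasts, filter, most alternatives, 28 gene lists and the rule for naming genes were fixed. The lists cover T cell stages and signals, other blood lineages, thymic stroma, cell cycle, chromatin complexes, metabolism, handling stress and sex-linked genes, and 27 had at least 3 tested members. Lists were tested with camera in limma at the preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. All camera calls at the preset value were lost when the correlation was estimated from the data, so the list results describe a shift of the members relative to other genes without allowance for their co-regulation. The rule named Ikzf1 and, within a stage, the 12 largest rises and 12 largest falls among called genes whose 2 IkL/L arrays both lay on 1 side of both WT arrays. It named 8 and 8 for the averaged contrast, 6 and 6 for the difference between DP and DN3 cells, 5 and 5 for each step, and up to 4 called members of a described list. Symbols of unnamed transcripts were skipped but kept their place in the count. The myeloid genes S100a8 and S100a9, and members named from lists with no call, were chosen after their values were seen.

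The alternatives were no brightness filter or one at the 75th percentile, the mean of a gene's probe sets, a trend and robust prior, array weights, arrays centred on their median, a second quantile normalization, the replicate number as a fixed block, the pool of mice as a random block, the arrays of the contrast alone, leaving out each array, a minimum log2 difference of 1, camera with an estimated correlation, and fry. After the arrays were examined, 4 were added: leaving out the 3 IkL/L replicate 2 arrays, whose Y-linked signal was at the floor, the difference between the 3' and 5' actin control probe sets as a covariate, a replicate block within each genotype, and, for genes that fall under the filter when an array is left out, the fit without that array on the genes that pass with all arrays. With the trend and robust prior, array weights and the pool as a random block, lists were tested with cameraPR in limma. It takes the moderated t of each gene, at the same preset correlation. A list call that changes under those settings may thus come from the change of test. The model was tested on simulated data of 11649 genes with the group sizes of the study. For the comparison in DN3 cells it recovered 11.9% of genes changed by 0.5, 80.6% of those changed by 1 and 98.5% of those changed by 2, with 6.62% of its calls false. For the averaged comparison it recovered 67.2%, 95.5% and 100% (5.91% false), and for the difference between DP and DN3 cells 1.49%, 44.8% and 92.4% (5.15% false). The simulated arrays varied independently, without shared pools or labelling series, and 11449 genes were left unchanged. These shares thus do not cover dependence between the real arrays. Figures were drawn with matplotlib.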

Results

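RNA was measured in thymocytes sorted from wild-type (WT) and IkL/L mice at 3 stages of T cell development. DN3 and DN4 cells are precursors that carry neither the CD4 nor the CD8 co-receptor, and DP cells carry both. The series calls the IkL/L cells Ikaros-deficient. Ikaros, the product of Ikzf1, is a zinc-finger transcription factor of lymphoid cells. Each of the 6 groups held 2 arrays, which gave 12 arrays in all, and the cells of 3 mice were combined for each sort. The array medians lay between 5.14 and 5.22 on the log2 scale, and the 75th percentiles between 7.34 and 7.57. The number of arrays limits the precision of every value given here. The comparisons ask which genes differ between the genotypes at each stage, whether that difference changes between stages, and how each genotype changes from one stage to the next.

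Stage and genotype each accounted for a separate axis of variation. The first principal component (PC1), with 68.9% of the variance over 11649 tested genes, set DP cells apart from DN3 and DN4 cells. The second (PC2), with 10.3%, parted the genotypes at every stage: the 6 WT arrays scored between 12.2 and 20.8 and the 6 IkL/L arrays between -21.0 and -13.7. The third, with 8.99%, separated DN3 from DN4 cells. Arrays of a group correlated across genes with r between 0.987 and 0.996 (genes are not independent replicates).

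**Figure D1:**
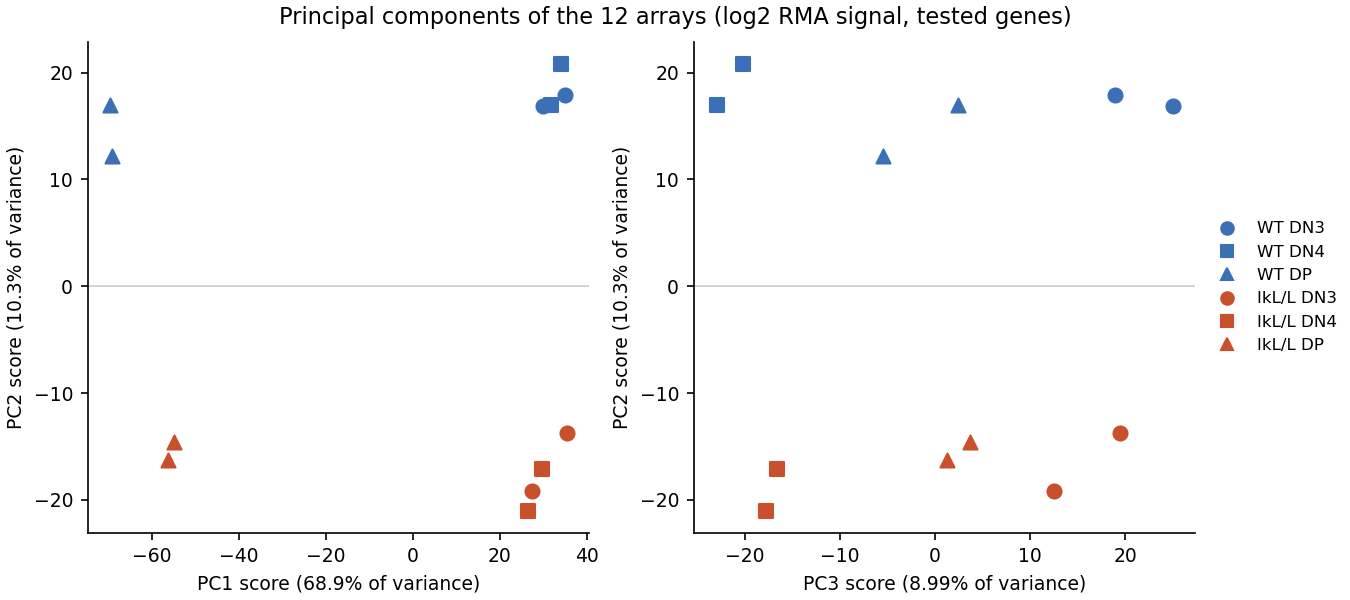
Scores of the 12 arrays on the first 3 principal components of log2 RMA signal over the tested genes, with 1 point per array, color for genotype and shape for stage. PC2 scores are positive on all WT arrays (12.2 to 20.8) and negative on all IkL/L arrays (-21.0 to -13.7).

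Ikzf1 itself was measured by 2 probe sets. The brighter one fell in IkL/L cells to 63.7% of WT in DN3 cells, 64.5% in DN4 cells and 61.7% in DP cells. On the log2 scale it averaged 11.88 ± 0.07 (SD, n = 2) in WT DN3 cells and 11.23 ± 0.01 in IkL/L DN3 cells, a difference of -0.65 (adjusted p = 0.0188 over all probe sets). The differences in DN4 and DP cells were -0.63 (adjusted p = 0.0202) and -0.70 (adjusted p = 0.00979). The dimmer one passed the test in DN4 cells alone, at -1.03 (adjusted p = 0.00799), against -0.29 (adjusted p = 0.548) in DN3 and -0.23 (adjusted p = 0.66) in DP cells. Where either probe set lies relative to the targeted part of the gene is not known here. Over genes, the call was lost without WT DN3 replicate 1 (adjusted p = 0.0626) or 2 (0.104) in DN3 cells, and without IkL/L DP replicate 2 (0.0544) in DP cells. In DN4 cells it was lost without WT DN4 replicate 2 (0.0952) and without IkL/L DN4 replicate 1 (0.0598) or 2 (0.0893).

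Some genes near the array floor in WT DN3 cells were strongly expressed in IkL/L DN3 cells. Lmcd1, a LIM-domain transcriptional cofactor, rose from 4.58 ± 0.09 to 10.03 ± 0.31 on the log2 scale (SD, n = 2), a difference of 5.45 ± 0.22 (SE; adjusted p = 1.22e-07). The WT level is below the array median, so this and other differences from or to such levels are lower limits of the change in RNA. Cttnbp2nl rose by 3.58, the ubiquitin ligase Trim2 by 3.54, Ptgfrn by 3.48, the Rac activator Dock1 by 3.32 and the membrane metalloproteinase Mmp14 by 3.23. Ctnnd1, which encodes the cadherin partner p120-catenin, rose by 3.12, Prom1 by 2.97, the small GTPase Rab34 by 2.93, App by 2.67 and the proteasome subunit Psma8 by 2.63. Cdh1, which encodes E-cadherin, fell from 7.93 ± 0.18 to 4.32 ± 0.12, a difference of -3.61 ± 0.14 (adjusted p = 1.22e-07). Trib2 (-3.20), the actin-severing protein gene Scin (-3.08), the tubulin gene Tubb2b (-3.01), Prr13 (-2.35), Lsp1 (-2.33), Rnf125 (-2.29), Ddc (-2.27), Pgam2 (-2.23) and Ptgs2 (-2.20) fell as well.

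In limma, 499 of 11649 genes passed an adjusted p of 0.05 in DN3 cells, 242 higher and 257 lower in IkL/L. The balance depended on the IkL/L arrays: without IkL/L DN3 replicate 1 there were 792 calls, 235 higher and 557 lower, and without replicate 2 there were 345, 233 higher and 112 lower. The count went to 205 without WT DN3 replicate 1 and to 272 without WT DN3 replicate 2. Without the 3 IkL/L replicate 2 arrays, which lack Y-linked signal, 207 were higher and 96 lower. The genes from Lmcd1 to Ptgs2 named above kept their calls when any 1 array was left out, except that Cdh1 and Ptgs2 passed the brightness filter through the 2 WT DN3 arrays alone and fell under it without either. With the tested genes held fixed both kept their calls there, and Ptgs2 was at -1.30 without WT DN3 replicate 1 and -3.09 without replicate 2. Ptgs2 lost its call when the DN3 arrays were fitted alone (adjusted p = 0.123). Other bright probe sets of the same gene gave 1.86 for Trim2 and 3.50 for Rab34, but 0.65 for Ctnnd1 (adjusted p = 0.269) and 0.42 (adjusted p = 0.592) and 0.0011 for Mmp14. With the mean of a gene's probe sets the difference was 1.19 for Trim2, 1.99 for Ptgfrn, 1.81 for Dock1, 1.22 for Mmp14, 1.64 for Ctnnd1, -1.14 for Trib2 and -1.15 for Ddc, each still called.

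The genes that mark the DN3 stage were lower in IkL/L DN3 cells as a list (camera adjusted p = 0.00199, median -0.29; adjusted p = 0.421 with an estimated correlation). Of its 23 tested members 3 fell and 1 rose: Cdh1, Spib (-1.88) and Trat1 (-0.55) were lower and Runx1 (0.76) was higher, and 6 changed when adjusted over the list alone, 5 of them lower. The list median was -0.47 without IkL/L DN3 replicate 1, -0.14 without replicate 2 and -0.53 with the mean of each gene's probe sets. The calls of Trat1 and Runx1 were lost without at least 1 array (adjusted p up to 0.341 and 0.282). MHC class II genes were higher (camera adjusted p = 0.0142; 0.421 with an estimated correlation), with H2-Aa at 1.94, H2-Ab1 at 1.44 and Cd74 at 0.85 among 3 risen and 1 fallen of 8, the last being H2-Ob at -0.78. Adjusted over the list alone, 5 rose and 2 fell. The same H2-Aa, H2-Ab1 and Cd74, with Tcf4 (0.60), were the 4 risen members of the 10 dendritic cell genes (camera adjusted p = 0.0164; 0.421 with an estimated correlation; 4 adjusted over the list alone). With the mean of each gene's probe sets the dendritic call was lost (0.054) and the list median went from 0.10 to -0.03; it was 0.19 without IkL/L DN3 replicate 2, 0.05 with arrays centred on their median, 0.06 with no filter and 0.28 with the filter at the 75th percentile. H2-Ab1 kept its call without each array, whereas H2-Aa, Cd74, Tcf4 and H2-Ob lost theirs without at least 5 arrays in turn (adjusted p up to 0.264, 0.213, 0.285 and 0.314).

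Stem-cell signalling and adhesion genes were higher in IkL/L DN3 cells (camera adjusted p = 0.0315, median 0.13; adjusted p = 0.421 with an estimated correlation), with Ctnnd1, the alpha-catenin gene Ctnna1 (adjusted p = 4.96e-05) and the integrin gene Itga6 (0.84) raised and Cd93 (-1.04) lowered among 14. Adjusted over the list alone, 6 rose and 2 fell. That list call was lost without WT DN3 replicate 1 (adjusted p = 0.108, median 0.06) or IkL/L DN3 replicate 2 (0.0557, median 0.20) and with the filter at the 75th percentile (0.0641, where the median was -0.02), the DN3 arrays alone (0.0598) and without all 3 IkL/L replicate 2 arrays (0.066), and the call of Itga6 without WT DN3 replicate 1 (0.152) or IkL/L DN3 replicate 1 (0.0514). The list median was 0.25 without WT DN3 replicate 2 and 0.08 with arrays centred on their median. Cell cycle genes had a median of 0.17 (camera adjusted p = 0.00199; 0.784 with an estimated correlation) although none of the 31 passed on its own, and the list call was lost without WT DN3 replicate 1 (0.114), where the median was 0.07. Myeloid cell genes, of which S100a8 differed by 2.08 (adjusted p = 0.361) and S100a9 by 1.62 without passing the test, had a median of 0.93 (camera adjusted p = 0.0454; 0.784 with an estimated correlation). Cebpb was the 1 called member of the 11, at -0.89 (lost without WT DN3 replicate 2, 0.14, or IkL/L DN3 replicate 2, 0.093), and 1 rose and 1 fell when adjusted over the list alone. The mean of the myeloid genes lay 1.36 above WT on IkL/L DN3 replicate 1 and 0.07 above it on replicate 2, and the list call was lost without replicate 1 (0.394, median 0.14), WT DN3 replicate 1 (0.114), IkL/L DN4 replicate 1 (0.0704, median 0.52) or WT DP replicate 1 (0.0629) or 2 (0.0632). It was lost as well with a second quantile normalization (0.108). By cameraPR the list was not called with the pool of mice as a random block (0.169), array weights (0.133) or the trend and robust prior (0.287). The median was 1.44 without IkL/L DN3 replicate 2 and 0.17 with no filter, where the list was called.

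In DN4 cells many of the same genes were raised by a similar amount. Trim2 was higher in IkL/L by 4.08 ± 0.32 (SE; 3.82 ± 0.03 in WT against 7.90 ± 0.56 in IkL/L, SD, n = 2; adjusted p = 1.93e-05), Dock1 by 3.89, Mmp14 by 3.53, Ptgfrn by 3.32 and Rab34 by 3.18. The cyclophilin gene Ppic (3.02), the non-muscle myosin gene Myh10 (3.00), Sertad4 (2.94), Psma8 (2.80) and Spin4 (2.71) followed. The deepest fall was that of Cd69, an early activation marker that is also induced by T cell receptor signals in the thymus, at -3.06 ± 0.48 (9.15 ± 0.32 in WT against 6.08 ± 0.59 in IkL/L; adjusted p = 0.00287). Trib2 (-2.48), Tubb2b (-2.37), Prr13 (-2.32), the cytotoxic granule gene Nkg7 (-2.29), Tktl1 (-2.05), Zfp982 (-2.04) and Lsp1 (-1.86) fell too. The co-receptor chain gene Cd8b1 (-1.65) and the chemokine receptor gene Ccr9 (-1.53) were lower in IkL/L, but DP stage genes were not called as a list (camera adjusted p = 0.494): of 27 members 3 fell and 3 rose.

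A total of 802 genes were called in DN4 cells, 513 higher and 289 lower. When the values were quantile normalized again, 1067 were called and the balance turned to 363 higher and 704 lower, while the median over all genes moved from -0.002 to -0.11; of the 802 genes 641 were called in both. The 75th percentile of signal was 7.34 and 7.42 on the WT DN4 arrays and 7.51 and 7.53 on the IkL/L DN4 arrays. The count fell to 333 and 246 without WT DN4 replicate 1 or 2 and to 318 and 261 without IkL/L DN4 replicate 1 or 2. Mid1 (3.03, higher), Tox2 (lower) and Nefh (-1.70) also passed, with adjusted p of 0.0382, 0.0117 and 0.00596. Their calls were lost without at least 1 array: for Nefh without WT DN4 replicate 1 (0.0675) or IkL/L DN4 replicate 2 (0.0754), for Tox2 without any 1 of the 4 DN4 arrays (0.0541 to 0.111), and for Mid1 without any 1 of 7 arrays (up to 0.283). The other bright probe sets of Mmp14 gave 0.52 and 0.09 in DN4 cells. With the mean of a gene's probe sets Mid1 was at 0.92 and lost its call (0.0838), while Trim2 (1.60), Dock1 (2.12), Mmp14 (1.38), Ptgfrn (1.72), Trib2 (-0.96) and Tox2 (-1.23) were smaller and still called.

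Markers of mature T cells were lower in IkL/L DN4 cells (camera adjusted p = 0.012, median -0.61; adjusted p = 0.647 with an estimated correlation). Of 18 members 4 fell, namely Cd69, the transcription factor gene Runx3 (-1.59), Cd52 (-1.37) and Ctla4 (-0.99), and 1 rose; 7 fell and 1 rose when adjusted over the list alone. Genes of gamma-delta T, NK and innate lymphoid cells were lower as well (camera adjusted p = 0.0115; 0.647 with an estimated correlation): Nkg7, the kinase gene Blk (-1.46) and Sox13 (-1.06) fell among 14, and the same number when adjusted over the list alone. The median of this list, -0.25, was -0.11 without WT DN4 replicate 2, -0.12 with the actin covariate and -0.77 with the filter at the 75th percentile. Hox and other Polycomb-silenced developmental genes had a median of -0.20 (camera adjusted p = 0.0115; 0.647 with an estimated correlation), with Hoxa7 (-0.89) lowered among 11 and 2 lowered when adjusted over the list alone; this list call was lost without WT DN4 replicate 2 (0.0808, median -0.13), and the median was -0.36 with the mean of each gene's probe sets. After quantile normalization these 3 list calls were lost. Cd69, Runx3 and Nkg7 kept their calls without each array, while Cd52, Ctla4, Blk, Sox13 and Hoxa7 lost theirs without at least 2 of the DN4 arrays in turn (adjusted p up to 0.105, 0.179, 0.0786, 0.14 and 0.0533).

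Cell cycle genes were higher in IkL/L DN4 cells (camera adjusted p = 5.55e-05, median 0.35; adjusted p = 0.647 with an estimated correlation). Of 31 members 4 rose and none fell: the thymidylate synthase gene Tyms (1.84), Rrm2 (0.61), Mki67 (0.53) and Mcm7 (0.46); 7 rose when adjusted over the list alone. Each of these 4 calls was lost without at least 6 arrays in turn, with adjusted p up to 0.289. After quantile normalization the list was still called (0.00246) with a median of 0.15. Oxidative phosphorylation genes had a median of 0.22 (camera adjusted p = 0.0115, or 0.647 with an estimated correlation). None of 22 was called over all genes or adjusted over the list alone. The list call was lost after quantile normalization (0.535, with a median of -0.01) and with the filter at the 75th percentile (0.0951). By cameraPR the list was not called with array weights (0.065) or the pool of mice as a random block (0.0548). Without IkL/L DN4 replicate 2, or without all 3 IkL/L replicate 2 arrays, the call was lost too and the median was 0.19.

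**Figure D2:**
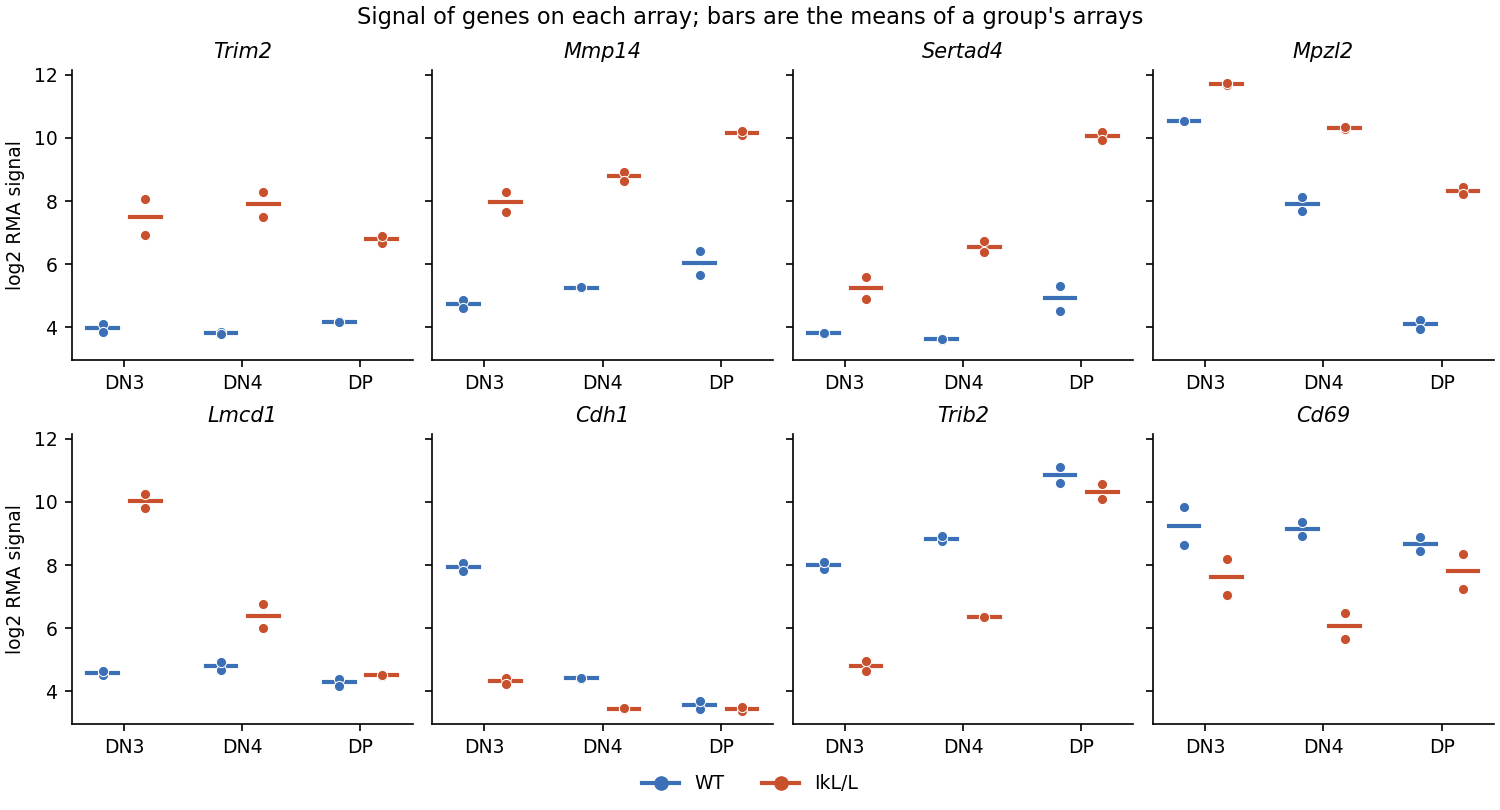
Log2 RMA signal of 8 genes on each array, by stage and genotype, with 1 point per array and a bar at the mean of each group's 2 arrays. Trim2, Mmp14 and Sertad4 are higher in IkL/L cells at all 3 stages, Lmcd1 and Cdh1 part the genotypes most in DN3 cells, and Mpzl2 declines from 10.54 to 4.10 between DN3 and DP cells in WT but from 11.70 to 8.33 in IkL/L.

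In DP cells the genes with the largest change rose. Sertad4 went from 4.92 ± 0.58 in WT to 10.06 ± 0.19 in IkL/L DP cells (SD, n = 2), a difference of 5.14 ± 0.26 (SE; adjusted p = 5.82e-07). The adhesion molecule gene Mpzl2 (4.22), Ppic (4.17), Mmp14 (4.14), the synaptotagmin gene Syt14 (3.55), the growth factor receptor gene Pdgfrb (3.50), Myh10 (3.21), the collagen receptor gene Ddr1 (3.00), Pwwp3b (2.96) and Tceal8 (2.93) were higher in IkL/L. Tdrp (-2.57), the interferon-induced gene Epsti1 (-1.95), the amino acid transporter gene Slc6a19 (-1.83), Tes (-1.79), Rufy2 (-1.78), Gpr174 (-1.77), Gramd3 (-1.68) and Ap3m2 (-1.68) were lower.

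The test called 697 genes in DP cells, 508 higher and 189 lower, and 89 of the 508 were below the array median on both WT DP arrays. The count was 385 without IkL/L DP replicate 1 and 438 without replicate 2. Cd163l1 (3.45 ± 0.87, adjusted p = 0.0369) and the co-stimulatory receptor gene Icos (-1.70, adjusted p = 0.0246) passed but varied between replicates. Cd163l1 had an SD of 2.68 in IkL/L, and its call was lost without any 1 of 7 arrays (adjusted p up to 0.169); without IkL/L DP replicate 2 the difference was 1.55 and without replicate 1 it was 5.35. Icos lost its call without WT DP replicate 1 (0.0603) or 2 (0.113) or IkL/L DP replicate 1 (0.141, with a difference of -0.90). Other bright probe sets gave 3.51 for Ddr1 (with 0.17, 0.06 and -0.01 on 3 more), 3.13 and 0.38 for Mpzl2, 1.32 and 0.39 for Mmp14, 0.62 for Pdgfrb and 1.37 for Cd163l1, and for Ap3m2 -0.63 and 0.12. With the mean of a gene's probe sets the difference was 0.95 for Ddr1, 2.58 for Mpzl2, 1.95 for Mmp14, 2.06 for Pdgfrb, 1.70 for Myh10 and -0.59 for Ap3m2, each still called.

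Notch target genes were higher in IkL/L DP cells (camera adjusted p = 0.000288, median 0.47; adjusted p = 0.61 with an estimated correlation). Of the 18 tested members 7 rose and none fell, led by Dtx1 (2.53 ± 0.31), the pre-T cell receptor chain gene Ptcra (1.63), Uaca (1.58) and Notch1 (adjusted p = 9.81e-05), which kept their calls without each array; 9 rose when adjusted over the list alone. The median was 0.30 with no filter and 1.01 with the filter at the 75th percentile. Genes of the DN3 stage, a list that shares Dtx1, Ptcra and Notch1 with the Notch targets, were higher (camera adjusted p = 0.0285; 0.761 with an estimated correlation), with 5 of 23 raised over all genes and 5 adjusted over the list alone. The DN3 list call was lost without WT DP replicate 2 (0.197) or IkL/L DP replicate 2 (0.0972), without all 3 IkL/L replicate 2 arrays (0.0695), with the mean of each gene's probe sets (0.123) and after quantile normalization (0.0851).

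Interferon response genes were higher in IkL/L DP cells (camera adjusted p = 4.32e-05, median 0.34; adjusted p = 0.61 with an estimated correlation). Usp18 (1.93), Rtp4 (1.45), Ifih1 (1.40) and Bst2 (1.29) led 5 risen members of 22 and kept their calls without each array, and 9 rose when adjusted over the list alone. With the filter at the 75th percentile the median was 0.58. The interferon-induced Epsti1, not on that list, fell. Cytosolic ribosomal protein genes had a median of 0.29 (camera adjusted p = 4.32e-05; 0.61 with an estimated correlation), with Rps19 (1.02) and Rpl10a (0.42) raised among 17 and 4 raised when adjusted over the list alone. Rpl10a lost its call without any 1 of 10 arrays (adjusted p up to 0.2), and the list lost its own after quantile normalization (0.0832, median 0.13). Cell cycle genes had a median of 0.32 (camera adjusted p = 0.000288; 0.785 with an estimated correlation), with Cenpf (0.59) and Cdc20 (0.52) raised among 31 and 5 raised when adjusted over the list alone. Both genes lost their calls without at least 8 arrays in turn (adjusted p up to 0.29 and 0.243), and the list call was lost without WT DP replicate 2 (0.197) or IkL/L DP replicate 1 (0.128, median 0.16). Oxidative phosphorylation genes had a median of 0.20 (camera adjusted p = 0.0059, or 0.61 with an estimated correlation), with none of 22 called either way. The list lost its call after quantile normalization (0.208, median 0.13) and without WT DP replicate 2 (median 0.24). By cameraPR the list was not called with array weights (0.0587) or the pool of mice as a random block (0.0512). Of 27 stem and progenitor cell genes on the array 18 were bright enough to test, and none of these was called higher at any stage, while Cd44 fell by 1.46 in DP cells and Hoxa7 by 0.89 in DN4 cells. Tal1, not tested, averaged 4.04 in WT and 5.12 in IkL/L DN3 cells. The mean of the erythroid genes lay 0.60 above WT on IkL/L DN3 replicate 1 and 0.25 below it on replicate 2, and the list was called higher in DN3 cells without the 3 IkL/L replicate 2 arrays (camera adjusted p = 0.00601, median 0.36).

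**Figure D3:**
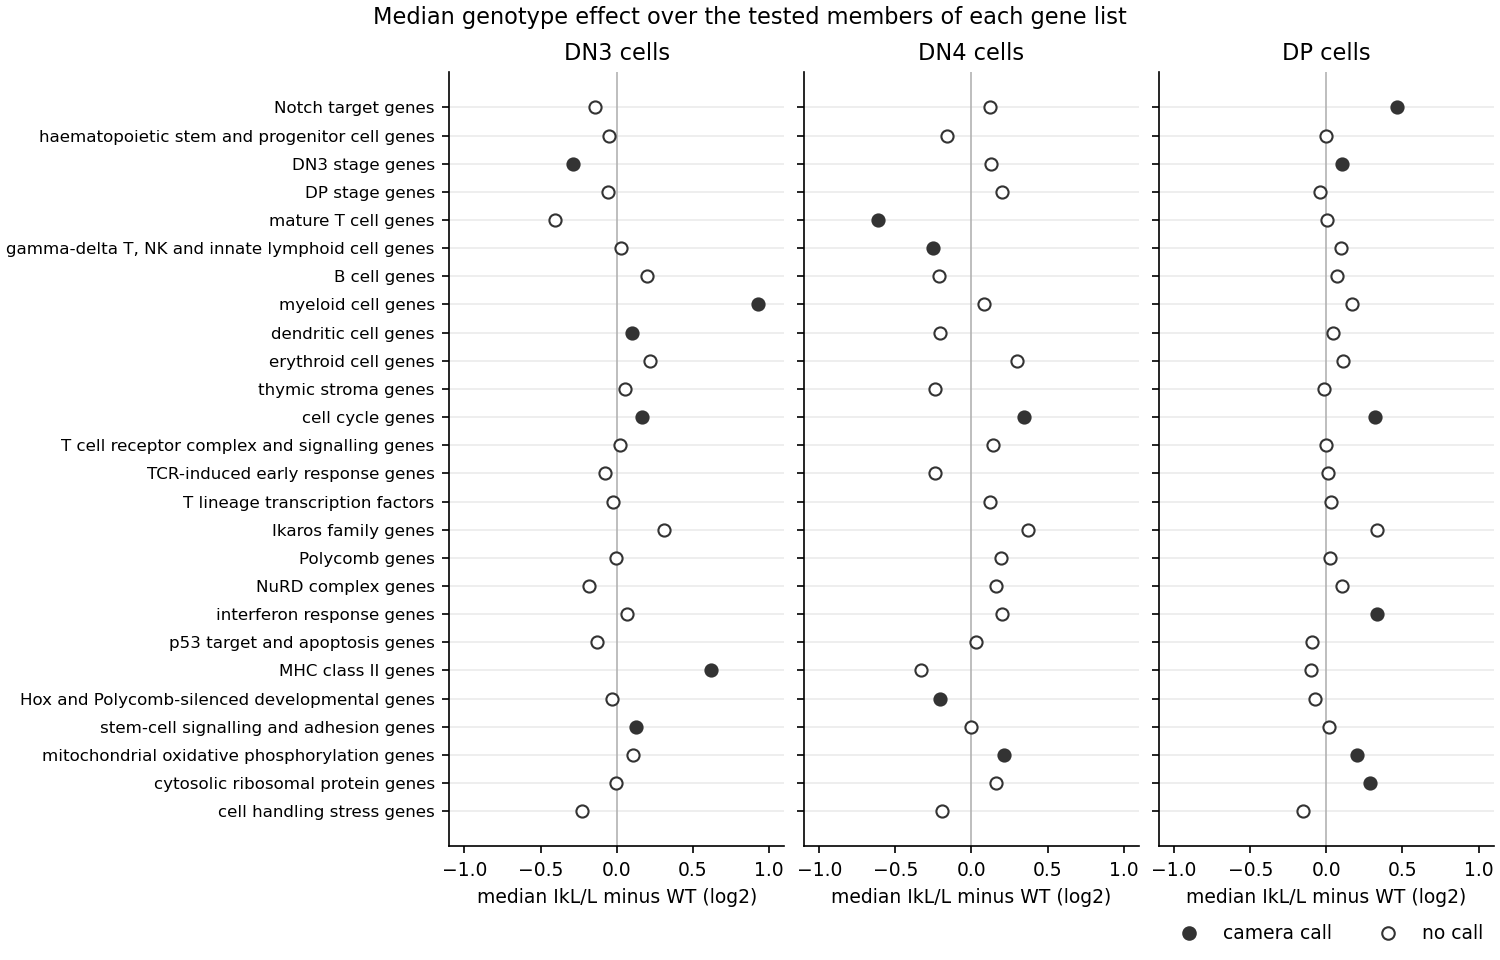
Median difference between IkL/L and WT (log2) over the tested members of 26 gene lists in DN3, DN4 and DP cells; filled points are lists called by camera at an adjusted p under 0.05 with the preset correlation. The medians lie between -0.61 (mature T cell genes in DN4 cells) and 0.93 (myeloid cell genes in DN3 cells), and no call holds with an estimated correlation.

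Much of the genotype difference fell on the same genes at different stages. DN3 and DN4 cells shared 174 genes called higher (10.7 expected if the calls were independent) and 101 called lower (6.38 expected), and 1 gene had opposite calls. DN4 and DP cells shared 192 higher (22.4 expected) and 48 lower (4.69 expected), with 6 opposite. DN3 and DP cells shared 138 higher (10.6 expected) and 55 lower (4.17 expected), with 10 opposite. At all 3 stages 121 genes were called higher and 29 lower. The effects correlated across genes with r = 0.652 between DN3 and DN4, 0.453 between DN4 and DP and 0.46 between DN3 and DP cells. Neither the expected counts nor r allow for mice shared between stages. Y-linked signal was at the floor on all 3 IkL/L replicate 2 arrays. Deviations of replicates correlated between DN3 and DN4 cells (r = 0.494 in IkL/L and 0.317 in WT). Differences between shared pools would recur across stages and add to the overlap. The 275 shared calls of DN3 and DN4 became 147 and 176 without WT DN3 replicate 1 or 2, 179 and 165 without WT DN4 replicate 1 or 2, and 177 and 169 without IkL/L DN4 replicate 1 or 2. The 240 of DN4 and DP became 139 and 143 without WT DN4 replicate 1 or 2 and 137 and 141 without IkL/L DN4 replicate 1 or 2, and the 193 of DN3 and DP became 99 without WT DN3 replicate 1.

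Averaged over the stages, Mmp14 was higher in IkL/L cells by 3.63 ± 0.14 (SE, adjusted p = 2.01e-08), with each of the 6 IkL/L arrays above the WT arrays of its stage. The SE and p values of the averaged comparison take the arrays as independent. They do not allow for mice shared between stages and need not hold the variation between mice. Trim2 (3.41), Dock1 (3.28), Ppic (3.23), Sertad4 (3.17), Ptgfrn (3.15) and Myh10 (2.93) were higher, and Trib2 (-2.07), Tubb2b (-2.06), Cd69 (-1.85), Prr13 (-1.80), Epsti1 (-1.75), Zfp982 (-1.65) and Gpr174 (-1.60) were lower. With the mean of a gene's probe sets the difference was 1.51 for Mmp14, 1.22 for Trim2, 1.74 for Dock1 and 1.71 for Ptgfrn. It was 1.79 for Myh10 and -0.75 for Trib2, and each of these was still called. Cell cycle genes were the list with the smallest p (camera adjusted p = 1.08e-06; 0.797 with an estimated correlation): 12 of 31 rose, among them Ccna2 (0.58), Rrm2 (0.48) and Cenpf (0.46), none fell, and 16 rose when adjusted over the list alone. Interferon response genes (camera adjusted p = 0.00416; 0.797 with an estimated correlation) had 8 of 22 raised, led by Ifih1 (0.99), Rtp4 (0.83) and Usp18 (0.83), with 11 raised and 2 lowered when adjusted over the list alone. Oxidative phosphorylation genes had 6 of 22 raised and ribosomal protein genes 2 of 17 (camera adjusted p = 0.00177 for both; 0.797 with an estimated correlation), or 10 and 2 when adjusted over the list alone. After quantile normalization the calls of these last 2 lists were lost (adjusted p = 0.343 for both, medians 0.05 and 0.03 against 0.17 and 0.14). With array weights the 2 lists were not called by cameraPR (0.0501 for both).

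The averaged comparison of 6 arrays with 6 called 1806 genes, 1050 higher and 756 lower. With the pool of mice as a random block 1189 were called, all among the 1806. After a second quantile normalization 1919 were called and more were lower, with 833 higher and 1086 lower. More were lower also without IkL/L DN3 replicate 1 (968 higher and 1055 lower) or WT DP replicate 1 (1014 higher and 1018 lower). The count was 1168 without WT DN3 replicate 1, 1197 without WT DN3 replicate 2, 1153 without WT DN4 replicate 2 and 1172 without IkL/L DN4 replicate 2.

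The genotype difference itself changed between DN3 and DP cells for some genes. Sertad4 differed by 1.43 in DN3 cells and 5.14 in DP cells, a change of 3.72 ± 0.37 (SE, adjusted p = 0.00045), and Mpzl2 by 1.16 and 4.22, a change of 3.06. Sertad4 lay below the array median on both WT DN3 arrays (3.79 and 3.83) and on WT DP replicate 1 (4.51). Both its differences are thus lower limits, and its change is neither exact nor a bound. Syt14 was below the array median in DN3 cells of both genotypes and rose in DP cells (3.55; change 3.34). Dtx1 had no call in DN3 cells at -1.08 and rose in DP cells (change 3.61), and Ddc, an aromatic amino acid decarboxylase gene, was lower in DN3 (-2.27) and higher in DP cells (1.31; change 3.58). Cdh1 was lower in DN3 (-3.61) and DN4 cells (-0.96) and near the array floor in DP cells of both genotypes (change 3.49). In the other direction Lmcd1 (change -5.24), Cttnbp2nl (-2.94) and Prom1 (-2.36) were raised in DN3 cells and below the array median in DP cells of both genotypes. For these genes, Cdh1 and Syt14 an effect could be measured at 1 of the 2 stages, so the change stands for that effect. The MHC class I gene H2-Q2 (-2.29) and the Wnt ligand gene Wnt8b (-2.20) also had more negative effects in DP cells. Mpzl2 on the WT DP arrays, Ddc on the IkL/L DN3 and WT DP arrays, and Wnt8b on the WT DN3 arrays lay below the array median. The changes of these genes are thus lower limits in size. With the mean of a gene's probe sets the change was 1.87 for Dtx1, 1.88 for Ddc, 1.27 for Mpzl2 and -1.25 for Wnt8b, each still called.

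The test of this difference called 202 genes, 161 with a more positive effect in DP than in DN3 cells and 41 with a more negative one. That balance was not kept without the 3 IkL/L replicate 2 arrays, which lack Y-linked signal: 80 genes were called, 40 in each direction, and 61 of them were among the 202. Without IkL/L DN3 replicate 1, 309 were more positive and 49 more negative. The count was 75 and 98 without WT DN3 replicate 1 or 2, 358 and 114 without IkL/L DN3 replicate 1 or 2, 123 without WT DP replicate 1 and 97 without IkL/L DP replicate 2. Tdrp (change -2.57, adjusted p = 0.044) lost its call without any 1 of 9 arrays (adjusted p up to 0.187). A single test of any difference between the 3 stages called 171 genes, and the difference between DN4 and DN3 cells 6. The 171 became 85 and 90 without WT DN3 replicate 1 or 2, 103 without WT DN4 replicate 2, 111 without WT DP replicate 1, 332 without IkL/L DN3 replicate 1, 108 and 110 without IkL/L DN4 replicate 1 or 2, and 85 without IkL/L DP replicate 2. Genes of the DN3 stage (camera adjusted p = 1.01e-07; 0.402 with an estimated correlation) and Notch targets (0.00168; adjusted p = 0.839 with an estimated correlation) had more positive effects in DP cells, with Spib (2.27), Ptcra (2.25) and Notch1 (1.45) called in addition to Dtx1 and Cdh1. Of the DN3 list 6 of 23 passed and 8 when adjusted over the list alone, and of the Notch targets 5 of 18 and 6, all of them more positive.

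**Figure D4:**
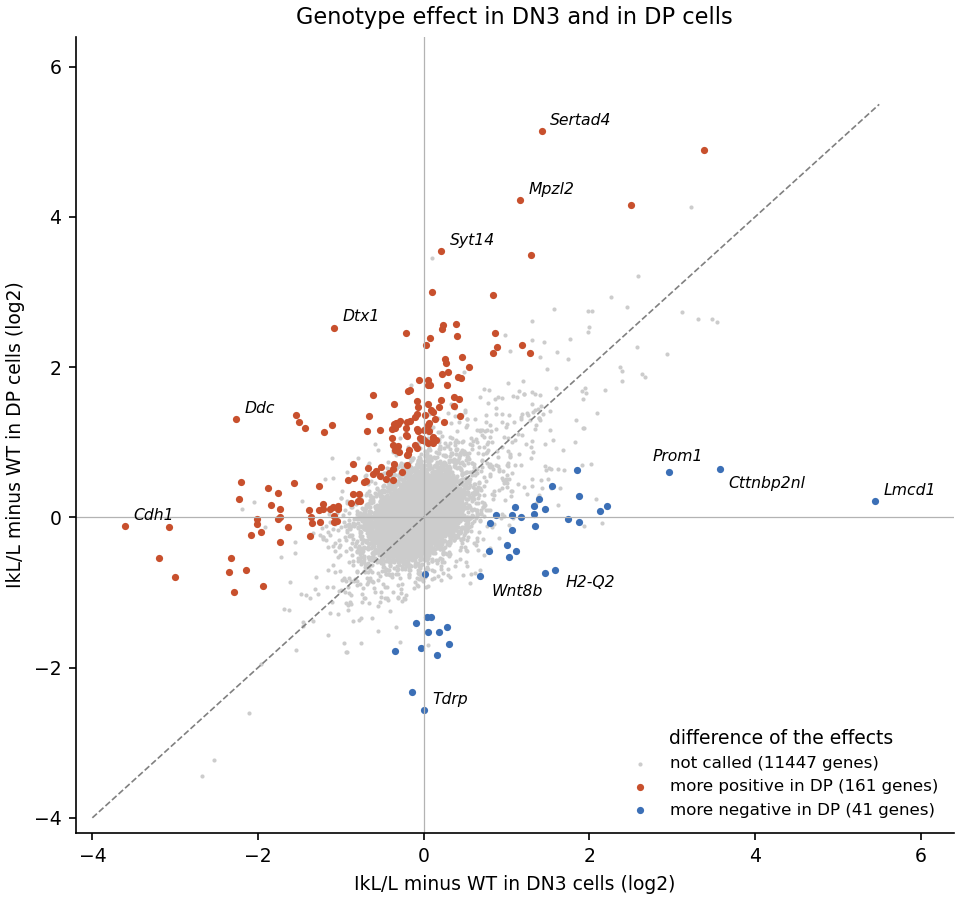
Difference between IkL/L and WT (log2) in DN3 cells (horizontal axis) against that in DP cells (vertical axis), with 1 point per tested gene; the dashed line marks equal effects, and the colored points are the 161 genes with a more positive and the 41 with a more negative effect in DP cells. Sertad4 and Mpzl2 lie above the line and Lmcd1 far below it.

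From DN3 to DN4, WT cells gained the co-receptor chain gene Cd8b1 (3.42), St6gal1 (2.63), Myo6 (2.53), Cd2 (2.38) and Gsn (2.30), and lost Khdc1a (-5.33), Scin (-5.03), the interleukin-2 receptor gene Il2ra (-4.74), Ctla2a (-4.37) and Pld4 (-3.94). IkL/L cells gained Cd8b1 by 2.33, Glcci1 (2.17), Tubb2b (1.94), Hemgn (1.88) and Maf (1.88), and lost Il2ra (-5.22), Ctla2a (-4.48), Khdc1a (-4.04), Lmcd1 (-3.64) and Atp8b4 (-3.50). From DN4 to DP, WT cells gained Spo11 (5.98), Cd8a (5.39), Slc7a11 (5.13), Dzip1 (5.07) and Cd4 (4.76), and lost Hspa1a (-5.95), Trgv1 (-5.55), Plac8 (-5.52), Cd163l1 (-5.29) and Trgv4 (-5.18). IkL/L cells gained Cd8a (5.89), Adam12 (4.87), Cd8b1 (4.73), Spo11 (4.71) and Abca1 (4.57), and lost Hspa1a (-5.88), Gja1 (-5.35), Hspa1b (-5.34), Plac8 (-4.49) and Gpr25 (-4.30). All 40 of these changes kept their call when any 1 array was left out.

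With the mean of a gene's probe sets some of the changes named above were smaller and still called. To DN4 they were St6gal1 (1.64) and Gsn (1.49) in WT, and Glcci1 (1.38) and Maf (0.88) in IkL/L cells. To DP they were Dzip1 (2.26) in WT, and Abca1 (1.63), Adam12 (2.79) and Gja1 (-3.30) in IkL/L cells. Maf was at 1.20 without the 3 IkL/L replicate 2 arrays. The step from DN3 to DN4 called 1078 genes in WT cells (181 higher and 897 lower) and 512 in IkL/L cells (140 higher and 372 lower). The step from DN4 to DP called 6638 genes in WT cells (2768 higher and 3870 lower) and 5298 in IkL/L cells (2270 higher and 3028 lower). Counts in different genotypes do not show that the steps differ. After a second quantile normalization the WT step to DN4 had 1064 calls, 383 higher and 681 lower. That WT count was 329 and 606 without WT DN3 replicate 1 or 2 and 414 and 576 without WT DN4 replicate 1 or 2, and the IkL/L count was 250 and 211 without IkL/L DN4 replicate 1 or 2. Without IkL/L DN3 replicate 1 the balance of the IkL/L step turned to 322 higher and 247 lower.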

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

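The splits of whole pools, the comparison with lists matched on WT DP cells and the test of the array floor among genes not called higher in DP cells were chosen only after the results were seen, and the fits without the 3 arrays lacking Y-linked signal or with the actin covariate after the arrays were examined.

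The genotype difference changed between DN3 and DP cells for 202 genes, and between any stages for 171, each by a test of the difference itself. The 12 genes that the naming rule takes for the change from DN3 to DP were Sertad4 (3.72), Dtx1 (3.61), Ddc (3.58), Cdh1 (3.49), Syt14 (3.34) and Mpzl2 (3.06), more positive in DP, and Lmcd1 (-5.24), Cttnbp2nl (-2.94), Tdrp (-2.57), Prom1 (-2.36), H2-Q2 (-2.29) and Wnt8b (-2.20), more negative. Some sizes depend on the probe set: with the mean of a gene's probe sets they were 1.87 for Dtx1, 1.88 for Ddc, 1.27 for Mpzl2 and -1.25 for Wnt8b. Cdh1, Lmcd1, Cttnbp2nl and Prom1 lay below the array median in DP cells of both genotypes, and Syt14 and Tdrp in DN3 cells, so their values hold the effect at the other stage and give no order among the 12. Sertad4 lay below the array median on both WT DN3 arrays and on WT DP replicate 1, so its change is not exact. Mpzl2 on the WT DP arrays, Ddc on the IkL/L DN3 and WT DP arrays, and Wnt8b on the WT DN3 arrays also lay below it. Their changes are thus lower limits in size. Tdrp lost its call without any 1 of 9 arrays (adjusted p up to 0.187).

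The median change of the effect from DN3 to DP was 0.31 for Notch target genes (camera adjusted p = 0.00168), or 0.77 with the filter at the 75th percentile. For DN3 stage genes it was 0.40 (1.01e-07), or 0.23 without IkL/L DN3 replicate 2. It was 0.46 for interferon response genes (0.00868), which lost the call without IkL/L DN3 replicate 1 (0.066) and had 0.30 without WT DP replicate 1 and 0.28 without IkL/L DP replicate 2. For cytosolic ribosomal protein genes it was 0.29 (0.00219), lost without WT DP replicate 2 (0.155) or IkL/L DP replicate 1 (0.0541) and after a second quantile normalization (0.0914, where it was 0.17). For MHC class II genes it was -0.42 (0.045), with the call lost without any 1 of 8 arrays. The call was lost too with the filter at the 75th percentile (0.952, where the median was 0.20). With the pool of mice as a random block the list was not called by cameraPR (0.0586). With an estimated correlation the adjusted p was 0.402 for DN3 stage genes and 0.839 for the other 4 lists. For interferon response genes the median change was 0.24 with no filter and 0.21 without the 3 IkL/L replicate 2 arrays. The median over all genes was 0.07, and 0.12 with arrays centred on their median.

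Among the 202 genes, the 161 with a more positive effect in DP cells may reflect the array floor, since a gene low in DP cells of both genotypes cannot fall there. Of the 161, 108 (67.1%, interval 59.2 to 74.3) were called higher in DP cells on their own, which argues against the floor for those 108. The 161 were chosen by a change that holds the same DP arrays, which favours such calls. The interval takes genes as independent and does not hold the variation between arrays. For the other 53 the floor stays open: 43.4% (29.8 to 57.7) lay below the array median on both WT DP arrays, as Cdh1 does. Leaving out IkL/L DN3 replicate 2, an array with a high ratio of 3' to 5' actin signal, kept the median effect of the 161 at 0.941 of its size (0.911 to 0.949 over genes). This cannot decide whether that array is the source. The genes were called with it, and a gene that differs on 1 array alone has a wide spread in its group and is seldom called. The balance of more positive to more negative calls shifted without that array and was lost without all 3 IkL/L replicate 2 arrays. A stage-dependent effect of the genotype, which the design names, stays open as a hypothesis, with the labelling series untested.

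Of 100 splits of the arrays within stages, drawn from 108, only the real one gave as many as the 1806 genes of the averaged comparison. The highest of the others gave 386. That share of 1 in 100 holds only if the 12 arrays are independent. Y-linked signal, at the floor on all 3 IkL/L replicate 2 arrays, goes against this. So does Xist in WT cells, which was higher on replicate 1 than on replicate 2 at each stage. Chance is thus not excluded. If the replicate number marks a pool of mice shared by the stages, splits of whole pools number 3, too few for a share under 0.05 (1 gave as many, the real 1806, and the highest other gave 0), and with the pool as a random block 1189 were called. Without the 3 IkL/L replicate 2 arrays, whose Y-linked signal was at the floor, the median effect of the called genes was 1.01 of its size (0.99966 to 1.02 over genes). The called effects were thus as large without those mice. That was largely fixed in advance: a gene that differs in 1 pool alone has a wide spread in its group and is seldom called. No conclusion on the sex of those mice is drawn from it. With the actin 3' to 5' difference in the model the median effect was 1.00 of its size (0.998 to 1.01 over genes). The same limit of gene choice holds there, so RNA integrity is not decided by it. The labelling series may run along the genotypes, and cannot be told apart from them here because the labels do not assign it.

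The 508 genes higher in IkL/L DP cells may come from DN cells in the sorted DP sample or from DN expression that persists into the DP stage. For the first, 12 genes were at least 16-fold higher in DN4 cells of both genotypes than in WT DP cells. They gave a share of IkL/L DN4 cells with a median of 2.62%. That share predicts a median rise of 0.05, against 0.94 in the 508, which were chosen for their rise. Of the 508, 99.6% (98.6 to 99.95) exceeded the prediction by more than 2 SE, and 91.1% did at the upper quartile share of 8.12%. Every called gene already rises by more than 2 SE, so with a small prediction this was nearly fixed. The share also averages 2 arrays that differed. Cd163l1 was at 5.56 and 9.36 on IkL/L DP replicates 1 and 2, and Hspa1a at 5.19 and 4.65. DN cells in the DP sample are thus not excluded. For the second, their median WT DN4 level of 7.52 lay inside the range of lists matched on all DP arrays (7.40 to 7.63) and above that of lists matched on WT DP arrays alone (6.87 to 7.13). Both matches use arrays that chose the genes, the first the IkL/L DP arrays where they are high and the second the WT DP arrays where they are low. For the 508 as a set, persistence thus cannot be told apart from a new rise. Single genes went both ways. Ppic was at 10.65 and 10.60 on the IkL/L DN4 arrays and at 8.76 and 9.02 on the IkL/L DP arrays. Syt14 was at 4.34 and 4.51 on the former and at 8.52 and 8.73 on the latter.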

How the results depend on the processing

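The added settings, chosen after the data were examined, are those without the pool lacking Y-linked signal, with the actin covariate, with a block within each genotype and with the tested genes held fixed when an array is left out. For 422 genes in their comparisons, 10017 values were recomputed: 9158 kept their direction and side of the threshold, 792 kept their direction and were no longer called, 64 were newly called and 3 reversed, all with the mean of a gene's probe sets (Hoxa9 in DN3 cells -0.76, Ptprk in DN4 cells 0.080, Ubash3a averaged 0.02). The median of mature T cell genes in DP cells turned to -0.18 without the pool lacking Y-linked signal, where the list was called lower (0.0323); it was called higher without IkL/L DP replicate 1 (0.00742, median 0.23). Among called lists, 4 medians changed sign as the call was lost: dendritic cell genes in DN3 (-0.03, mean of probe sets), stem-cell signalling and adhesion genes in DN3 (-0.02) and MHC class II genes for DP minus DN3 (0.20), both with the 75th percentile filter, and oxidative phosphorylation genes in DN4 (-0.01, second quantile normalization). The cause of the changes was not tested, except that fewer genes, fewer arrays or a further threshold leave fewer calls by construction.

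Cdh1, Ptgs2, Tktl1, Syt14 and Pwwp3b fell under the filter without an array of their bright group and kept their calls with the tested genes held fixed. Without each array in turn, where the lone array of a group is assumed to vary like the other groups, the calls ranged over 205 to 792 in DN3, 246 to 1114 in DN4 and 385 to 825 in DP cells. They ranged over 1153 to 2032 averaged, 75 to 358 for DP minus DN3 and 85 to 332 for any stage. The steps gave 329 to 1327 and 5397 to 6892 in WT and 211 to 592 and 4135 to 5564 in IkL/L cells. Shared calls ranged over 147 to 320 (DN3 and DN4, 275 with all arrays), 137 to 302 (DN4 and DP, 240) and 99 to 206 (DN3 and DP, 193). Lists called ranged over 3 to 8 in DN3 (6 with all arrays), 4 to 7 in DN4 (5), 3 to 9 in DP (6), 4 to 5 averaged (4) and 3 to 7 for DP minus DN3 (5).

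With no brightness filter 10 lists were called in DN4. With the filter at the 75th percentile the calls were 313 in DN3, 508 in DN4, 127 for DP minus DN3, 109 for any stage and 183 shared by DN3 and DN4. Array weights gave 1604 in DN4 and 2157 for the WT step to DN4. A second quantile normalization left 1 list in DN4, 3 in DP and 2 averaged. The pool as a random block gave 1189 averaged and 293 for any stage. The arrays of the contrast alone gave 272 in DN3, 1433 in DN4, 344 in DP, 102 for DP minus DN3, 1983 and 221 for the steps to DN4 in WT and IkL/L, and 101 shared by DN3 and DP; for the averaged and any-stage tests this setting equals the fit of all arrays and was not run.

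A log2 difference of at least 1 left 242 in DN3, 262 in DN4, 295 in DP, 191 averaged, 345 and 2861 for the WT steps, 223 and 2104 for the IkL/L steps, and 138, 111 and 91 shared. Without the pool lacking Y-linked signal there were 303 in DN3, 404 in DN4, 1189 averaged, 80 for DP minus DN3, 222 for the IkL/L step to DN4 and 77 for any stage, with 8 lists averaged and 11 for DP minus DN3. The actin covariate gave 1333 in DN4, 1048 in DP, 1806 for the WT and 815 for the IkL/L step to DN4, with 8 lists in DN4 and 9 for DP minus DN3. With an estimated correlation 0 lists were called in each of the 5 contrasts. With fry 0 were called in DN4, 8 averaged and 1 for DP minus DN3.

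The replicate numbers do not state a pairing. With the replicate block over all arrays the calls were 470 in DN3, 736 in DN4, 689 in DP, 1721 averaged and 170 for DP minus DN3, and a replicate block within each genotype gave 293 for any stage. Deviations of replicates from their group mean correlated across genes between stages of a genotype with r of 0.147 to 0.317 in WT and 0.015 to 0.494 in IkL/L cells, and between genotypes within a stage with r of -0.097 to 0.058.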

Other observations

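The tests of this part were fixed before their results were seen, while the genes named from lists without a call were chosen after.

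Genes of the Ikaros family and of p53 responses also differed between the genotypes. Ikzf3, which encodes Aiolos, was higher in IkL/L DN3 cells by 1.41 ± 0.16 (adjusted p = 0.000258) and in DN4 cells by 0.70, and Ikzf2, which encodes Helios, was higher in DP cells by 0.65. The Ikaros family list was not called at any stage by camera (adjusted p = 0.118, 0.341 and 0.525 in DN3, DN4 and DP cells), but was by fry in DN3 (0.00982) and DP cells (0.0398) and averaged over stages (0.00334), and its mean lay above WT by 0.14 to 0.32 on each of the 6 IkL/L arrays. Pmaip1, which encodes the death protein Noxa, was higher at each stage, by 1.26, 1.13 and 1.37, and Cdkn1a, a cell cycle inhibitor gene, by 0.72 in DN4 and 1.24 in DP cells. Bbc3 (-0.61 in DN4) and Sesn2 (-0.57 in DP) were lower, and the list of p53 targets and apoptosis genes was not called at any stage (adjusted p = 0.416, 0.631 and 0.903). Pmaip1 at each stage, Ikzf3 in DN3 cells and Cdkn1a in DP cells kept their calls without each array, while Ikzf3 in DN4, Ikzf2, Cdkn1a in DN4, Bbc3 and Sesn2 lost them without at least 3.

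Single genes of other lineages were raised in IkL/L DP cells without their lists. The granzyme gene Gzma rose by 2.11 and the gamma chain segment gene Trgv4 by 1.83, while the gamma-delta, NK and innate list was not called (camera adjusted p = 0.437). Trgv4 was also bright on the WT DN3 (12.6 and 12.2) and WT DN4 arrays (11.1 and 10.8). Its signal in DP cells thus need not come from another lineage. The keratin gene Krt18 rose by 1.63 and the collagen gene Col1a2 by 1.31, with thymic stroma genes not called (0.794). The MHC class II genes H2-Ab1 (1.38) and H2-Oa (1.17) rose and H2-Ob (-1.36) fell. All of these genes kept their calls without each array, and H2-Ab1 lost its call with the mean of probe sets (0.0586). IkL/L DP replicate 2 stood apart from replicate 1 in markers of other cells: relative to WT the mean of the gamma-delta, NK and innate genes was 0.53 against 0.09, of mature T cell genes 0.44 against -0.29, of myeloid genes 0.48 against -0.29 and of B cell genes 0.33 against -0.03. Cd163l1, which was at 8.91 to 9.31 on the WT DN3 and DN4 arrays, was at 9.36 on IkL/L DP replicate 2 against 5.56 on replicate 1. Without replicate 1 the gamma-delta, NK and innate list (camera adjusted p = 0.00545) and mature T cell genes (0.00742, median 0.23) were called higher in DP cells, while without the 3 IkL/L replicate 2 arrays mature T cell genes were called lower (0.0323, median -0.18).

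For the remaining lists the smallest camera adjusted p over the 3 stages was 0.0682 for stem and progenitor cell genes and for Polycomb genes, 0.0715 for early T cell receptor response genes, 0.106 for B cell genes, 0.183 for Y-linked genes, 0.205 for T cell receptor complex genes, 0.24 for handling stress genes, 0.327 for erythroid genes and for NuRD complex genes, 0.46 for T lineage transcription factors and 0.494 for DP stage genes. Under another setting some of these were called in DN4 cells: stem and progenitor cell genes lower with the mean of probe sets (0.0078) or no filter (0.0378) and without IkL/L DN3 replicate 1 (0.0356) or IkL/L DN4 replicate 1 (0.0363), early T cell receptor response genes lower without WT DN4 replicate 1 (0.0251) or IkL/L DN4 replicate 2 (0.0033), thymic stroma genes lower without WT DN4 replicate 1 (0.012), and Polycomb genes higher with no filter (0.0026) and without IkL/L DN4 replicate 1 (0.0477). B cell genes were called higher in DN3 cells with the mean of probe sets (0.0333), and Y-linked genes lower in DP cells without IkL/L DP replicate 1 (0.00545). Erythroid genes were called higher in DN3 cells without the 3 IkL/L replicate 2 arrays (0.00601, median 0.36), and their mean relative to WT was 0.60 and 0.76 on IkL/L DN3 and DN4 replicate 1 against -0.25 and -0.11 on replicate 2. In DN4 cells T cell receptor complex genes were called higher with no filter (camera adjusted p = 0.0227) or the actin covariate (0.021). Early T cell receptor response genes were called lower there with the filter at the 75th percentile (0.0158) or the actin covariate (0.021). Thymic stroma genes were called lower there with no filter (0.0172) or the actin covariate (0.021). The X inactivation list holds 1 gene and was not tested. Signs can differ within a list: stem and progenitor genes in DN3 cells had a median of -0.05 and a mean of -0.02 where camera pointed upwards.

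The arrays differed in the sex of the mice they appear to hold. Eif2s3y, a Y-linked gene, was at 2.82, 3.12 and 2.95 on the 3 IkL/L replicate 2 arrays and between 7.78 and 9.58 on the other 9, and Xist was between 12.6 and 12.7 on those 3 arrays and between 10.3 and 12.4 on the rest. In WT DN3, DN4 and DP cells Xist was at 12.1, 11.5 and 12.4 on replicate 1 against 11.3, 10.3 and 11.4 on replicate 2. Eif2s3y was at 8.27, 7.78 and 9.27 against 8.73, 8.55 and 9.58. The replicates of WT thus differed in the same direction at each stage, as pools shared by the stages would. The 3 IkL/L replicate 2 arrays had a log2 difference between 3' and 5' actin signal of 2.86, 2.39 and 2.64, against 1.74 to 2.29 on 8 others and 2.86 on WT DP replicate 1. For the Gapdh control probe sets it was 2.73, 2.54 and 3.37 on those 3 arrays. It was 2.01 to 2.53 on the other DN arrays and 3.02 to 3.83 on the other DP arrays. The Gapdh difference thus parted DP from DN arrays more than those 3 arrays from the rest.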
